A study of Mus musculus with 6 samples.

How the data were processed

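RNA was measured by sequencing in 6 libraries of Nestin-GFP-positive cells sorted from the dermis and attached subcutaneous white fat of 3-day-old mouse pups. Nestin-GFP is a reporter that marks cells in which the Nestin gene regulatory sequence is active, pericytes among them. Per the labels' protocols, the epidermis was removed after cold trypsin, the rest was digested with collagenase, hair follicles were spun out at low speed, and GFP-positive single cells were sorted. The 3 control mice carried the reporter alone. The 3 mutant mice carried the reporter, the Nestin-Cre recombinase and 1 copy of a Pdgfra allele with the activating change D842V. The labels put "[S]" before the name of that change, and its meaning is not given in the sources used here. The control genotype as labelled lacks Nestin-Cre, so the comparison holds the recombinase and the allele together. Per the labels' protocols, each genotype was represented by 3 mice, and the indexed libraries were pooled for sequencing. No batch, litter or strain is given in the sources used here.

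The authors deposited 1 file of whole-number read counts per gene for each library. Per the submitters' processing notes, the genome build was mm9 and the tools were FastQC, cutadapt 1.1, TopHat2 2.0.4, HTSeq 0.5.3 and DESeq2, named without role or order. The strand setting of the counting is not given in the sources used here, so a gene and its antisense partner could not be told apart. Each file held 37991 gene rows and 5 rows that name no gene. Those 5 rows stayed out of library sizes and tests. They took between 36.9% and 41.7% of the reads listed in each file, most of them reads assigned to no annotated feature.

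Gene symbols were matched by identifier for 32919 rows, 86.7% of all gene rows and 99.3% of the counts. The reference in hand was a later build than mm9, so it was used for symbols, gene types, exon lengths and distances between neighbouring genes, and no coordinate is printed. Gene counts per library ran from 11912469 to 18792939. At that depth the limit that a count of 0 allows, 3 counts, lay between 0.16 and 0.252 CPM, the usual unit of counts scaled to a common library total. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. Pairs of libraries of 1 group differed by more than sampling noise, with a chi-square per degree of freedom of 4.73 to 13.3 over genes with at least 10 counts in the pair, so all 6 counted as separate samples.

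The test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Counts were scaled by TMM, filtered with filterByExpr at its defaults of a minimum count of 10 and a minimum total of 15, and tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F test with robust fitting and group as the only term. A gene was called when its adjusted p (Benjamini-Hochberg) was under 0.05. Log2 fold changes are mutant over control, and intervals are at the 95% level from the same fit. CPM values are given as mean ± SD of 3 libraries. Exact permutation of 3 against 3 libraries cannot give a two-sided p under 0.1, so gene tests borrow their estimate of spread across genes. On simulated counts for 14880 genes with 200 genes changed and a further list of 20 genes raised together by 1.5-fold, the test recovered 46.3% of the first set's genes changed 1.5-fold, 80.3% of those changed 2-fold and 96.9% of those changed 4-fold, and 19 of the 20. In that simulation, run with 1 seed, 18 of 184 calls were false, 9.78%, or 10.9% without the calls of that list, above the 5% that the threshold aims at. The simulation changed far fewer genes than the 2670 called in the data. Recovery and the false share depend on that number, so they may not carry over.

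Gene lists numbered 26, of which 14 were primary and 12 held markers of other cell types or of RNA and dissociation state. A list with at least 5 tested members was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and p-values were adjusted over 24 lists. The test was repeated with a correlation estimated from the data. The lists were also tested with fry, which asks whether a list shifted in a common direction, where camera compares it with the other genes. Hmgcs1, Hbb-b1, Hbb-b2 and Ahsp of the lists matched no symbol. Calls within 10 Mb of Pdgfra were compared with the rest by Fisher's exact test.

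Named genes were Pdgfra, Pdgfrb and Nes. To these came the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM, no overlap between groups and a symbol that is neither Gm plus digits nor ends in Rik. Each primary list gave its 3 called members with the smallest adjusted p, or its 2 most abundant members where none was called, and each other list gave 1 member. Of the genes so named, 1 is not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

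Alternatives were other scalings (RLE, upper quartile, library size), no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with and without sample weights, the replicate number as a block, each library left out in turn, a minimum of 2-fold, and removal of sex-linked genes. Removal of a gene length trend by loess, counts of list members under each alternative and list medians with each library left out were added after seeing the data. Pseudogenes were aligned to protein-coding transcripts of GENCODE M21 with BLAST 2.17.0.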

Results

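Nestin-GFP-positive cells of neonatal skin and its fat layer were compared between 3 control mice and 3 mice in which 1 copy of Pdgfra carried the constitutively active change D842V. The title of the series calls the cells pericytes, the mural cells of small vessels. Gene counts came to 15839701, 11912469 and 15493190 in control replicates 1 to 3 and to 15321022, 15110824 and 18792939 in mutant replicates 1 to 3. The most abundant gene in every library was Col3a1, a fibrillar collagen, with 4.61% to 5.69% of gene counts. The correlation of log2 CPM over genes was 0.984 to 0.990 within groups and 0.970 to 0.980 between groups. The first principal component held 48.8% of the variance and separated the groups, and the second, with 18.2%, set control replicate 1 apart.

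The receptor gene that carried the mutant allele was lower in every mutant library. Pdgfra (ENSMUSG00000029231), the receptor for several platelet-derived growth factors, fell from 844 ± 21.1 to 358 ± 11.9 CPM (SD, n = 3 per group). The log2 fold change was -1.24 (95% interval -1.41 to -1.07), with an edgeR adjusted p of 2.75e-06. The related receptor Pdgfrb had 239 ± 21.2 CPM in controls and 229 ± 10.3 CPM in mutants, with an edgeR adjusted p of 0.641 (log2 fold change -0.06, and 0.00 without control replicate 1). Nes, the gene behind the sorting reporter, had 74.4 ± 5.83 and 84.3 ± 13.5 CPM, with an edgeR adjusted p of 0.28. Gene counts do not tell the mutant from the normal allele, so they do not show which allele's transcript was lower. Among genes within 10 Mb of Pdgfra, Pdgfra itself included, 10 of 72 were called, 13.9% against 17.8% elsewhere. The odds ratio was 0.746 (95% interval 0.341 to 1.47, Fisher's exact two-sided p = 0.443).

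**Figure D1:**
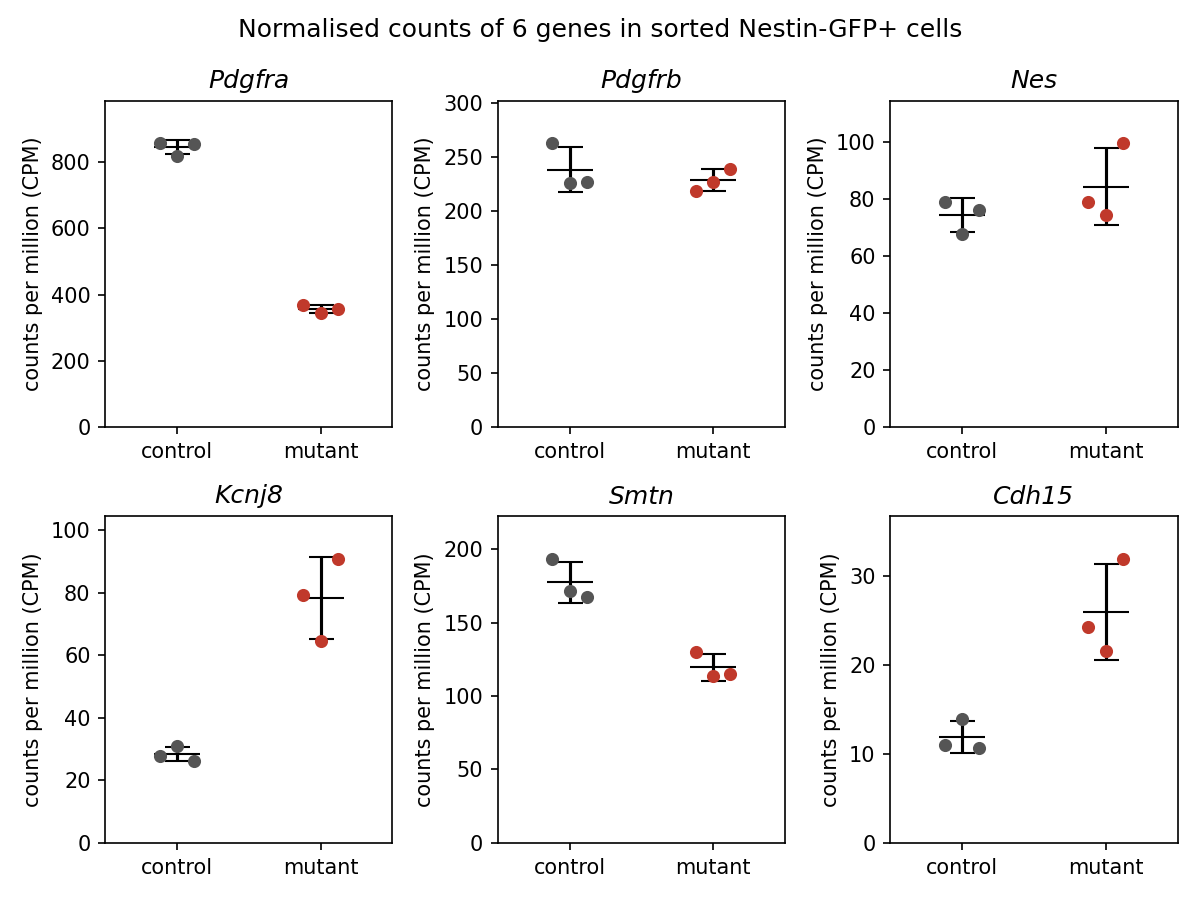
CPM (vertical axes, from 0) of 6 genes in control and mutant libraries. Points are single libraries, long bars the mean and whiskers the SD of 3 libraries. Pdgfra and Smtn were lower and Kcnj8 and Cdh15 higher in all mutant libraries than in all controls, while Pdgfrb and Nes overlapped.

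Members of the PDGF family moved both ways. Of 6 tested genes, Pdgfra among them, 2 rose and 2 fell, and the numbers adjusted over the list alone were also 2 and 2. The ligand genes Pdgfa (19.2 ± 1.5 to 27.3 ± 3.46 CPM, log2 fold change 0.51, edgeR adjusted p = 0.0099) and Pdgfc (log2 fold change 0.65) rose, and Pdgfd fell by 0.81 on the log2 scale. Pdgfc lies outside the rule for named genes and was chosen after its values were seen. The call of Pdgfa was lost without mutant replicate 3 (adjusted p = 0.0509), where the rises numbered 0, and without control replicate 3 they numbered 1. The list as a set was not called by camera (adjusted p = 0.703), and its median of 0.17 and mean of -0.09 differed in sign. The median was -0.01 without mutant replicate 3 and 0.07 without control replicate 3.

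Across all genes, 1298 were higher and 1372 lower in mutant cells out of 15035 tested by edgeR, and most changes were modest. The median absolute log2 fold change of the called genes was 0.48, and 222 genes were at least 2-fold higher and 170 at least 2-fold lower. The groups did not overlap in 5674 tested genes, against a chance share of 10%. The counts fell to 776 higher and 881 lower without control replicate 2, to 679 and 807 without control replicate 3, and to 658 and 753 without mutant replicate 3.

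The largest rises named by the rule included genes of striated muscle and of vessels. Fcna, a lectin of the innate immune system, rose from 4.47 ± 1.28 to 16.7 ± 3.33 CPM (log2 fold change 1.90). Myog, a transcription factor of muscle differentiation (1.79), the sarcomeric genes Actc1 (1.78), Acta1 (1.74) and Ttn (1.48), and Msc (1.51) followed. Akr1c18, a hydroxysteroid dehydrogenase (1.68), Lyve1, a lymphatic endothelial receptor (1.49), Kcnj8, a potassium channel subunit of pericytes (1.47), and Ptgis, the prostacyclin synthase (1.46), completed the 10. Their edgeR adjusted p-values lay between 7.59e-05 and 0.0278. The call of Myog was lost without mutant replicate 2 (largest adjusted p over alternatives 0.0635). The call of Acta1 was lost with no filter and without control replicate 3 or any 1 mutant library (largest 0.0879).

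The largest falls named by the rule began with Rps18-ps3, a processed pseudogene of a ribosomal protein gene, with 16.8 ± 1.92 CPM in controls and 0.398 ± 0.181 CPM in mutants (log2 fold change -5.41, edgeR adjusted p = 1.25e-07). Its sequence is 99.3% identical to the transcript of Rps18, so its reads are uncertain. The coagulation factor gene F5 fell by 3.09 on the log2 scale, from 18.6 ± 11.8 to 2.21 ± 0.899 CPM, a call lost with limma-voom, with no filter and without control replicate 3 or any 1 mutant library (largest adjusted p 0.142). The inducible heat shock genes Hspa1b (-2.40) and Hspa1a (-1.86), near-identical copies whose reads are therefore uncertain, fell as well. Nabp1 (-2.09), the basement membrane collagen gene Col4a6 (-1.98), Gldn (-1.96), Cadps (-1.93), the BMP antagonist gene Grem1 (-1.82) and the neuronal activity gene Arc (-1.81) made up the rest.

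Of 20 tested pericyte markers 6 rose, none fell and 14 were not called (7 rose and 0 fell adjusted over the list alone). Of 17 contractile genes of smooth muscle none rose and 7 fell (0 and 8 adjusted over the list alone). The lists were not tested against each other. Kcnj8 rose from 28.4 ± 2.32 to 78.2 ± 13.2 CPM, and Abcc9, which encodes the channel's partner subunit, from 66.4 ± 5.82 to 119.6 ± 11.2 CPM (log2 fold change 0.85). Art3 rose by 0.74 on the log2 scale. The abundant pericyte markers Rgs5 and Cspg4, chosen after their values were seen, had log2 fold changes of -0.72 and -0.26 and were not called (edgeR adjusted p = 0.181 and 0.0957). Smtn, a smooth muscle actin-binding protein, fell from 178 ± 14 to 119.5 ± 9.06 CPM (log2 fold change -0.57), Tpm1, a tropomyosin, by 0.42 and Casq2, a calcium store protein, by 1.77. The median of the contractile list was -0.50, and it was -0.36 without control replicate 1 and -0.34 without mutant replicate 2. Camera called the contractile list lower (adjusted p = 0.000115). That call was lost with an estimated correlation, adjusted p = 0.706. The pericyte list was not called (median 0.14, adjusted p = 0.1). It was called higher without control replicate 1 (adjusted p = 0.0424) and without mutant replicate 2 (0.0282). Its median was 0.24 without mutant replicate 2 and 0.03 without mutant replicate 3. Falls among contractile genes numbered 3 without control replicate 3 and 4 without mutant replicate 3, and rises among pericyte markers 3 without control replicate 2 or mutant replicate 3. Without control replicate 3, 1 pericyte marker was lower.

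Matrix genes and fibroblast markers moved in both directions. Of 36 collagen and other matrix genes 4 rose and 3 fell, also when adjusted over the list alone. Postn, a matrix protein of wounds and periosteum, rose from 3638 ± 249.9 to 5028 ± 275 CPM (log2 fold change 0.47), and Ogn (0.46) and Fbln1 (0.52) rose too. The set was not called (median -0.09, adjusted p = 0.31). It was called lower without mutant replicate 1 (adjusted p = 0.0400), and without mutant replicate 2 its direction turned (0.923) and the falls numbered 1. The median was -0.16 without mutant replicate 1, -0.03 without mutant replicate 2 and -0.04 without control replicate 1. Of 15 basement membrane genes 1 rose, Nid1, by 0.38 on the log2 scale, also when adjusted over the list alone, and the set was not called (adjusted p = 0.417). The call of Nid1 was lost without control replicate 2 and without mutant replicate 3 (largest adjusted p 0.0793), and without control replicate 1 the rises numbered 2. Of 23 fibroblast and adipose progenitor markers 5 rose and 1 fell, also over the list alone, and the set was not called (median 0.17, adjusted p = 0.105). Clec3b rose from 125 ± 10.9 to 235 ± 12.1 CPM (log2 fold change 0.91), Gsn rose by 0.32, and Dpp4, a marker of early progenitors, fell by 0.59. Rises in this list numbered 3 without control replicate 2, 1 without control replicate 3, and 2 without mutant replicate 1 or 3. Without mutant replicate 2 the list was called higher (adjusted p = 0.0299), and without control replicate 3 its median was 0.11. The call of Gsn was lost without control replicate 2 or 3 and without mutant replicate 1 or 3 (largest adjusted p 0.0803).

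Among 16 genes of matrix metalloproteases and their inhibitors 1 rose and 2 fell, also over the list alone, with Adamts4 at -0.47, Adamts2 at -0.28 and Mmp9 at 1.05, and the set was not called (adjusted p = 0.787). Its median of -0.01, between -0.04 and 0.00 with 1 library left out, and mean of 0.02 differed in sign. Mmp9 lost its call in 12 of 17 alternatives, each library left out among them (largest adjusted p 0.178). Falls numbered 0 without control replicate 2 or 3 and 1 without control replicate 1 or mutant replicate 2 or 3. Adamts2 lost its call without each of these libraries and with the length trend removed (largest adjusted p 0.123) and Adamts4 without control replicate 2 or 3 (0.0672).

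Genes of fat cells rose in part. Of 25 tested genes of adipogenesis and adipocytes 5 rose and 1 fell (7 and 1 adjusted over the list alone). Zfp423, a regulator of preadipocytes, rose from 51.1 ± 6.5 to 77 ± 6.58 CPM (log2 fold change 0.59), and Klf15 rose from 0.511 ± 0.258 to 2.42 ± 1.17 CPM (2.17). Fasn, the fatty acid synthase, fell by 0.33. Camera called the list higher (median 0.59, adjusted p = 0.00545), a call lost with an estimated correlation, adjusted p = 0.741. Mutant replicate 2 stood apart in this list. Cfd, chosen after its values were seen, had 111 CPM there against 10.9 and 6.28 CPM in the other mutant libraries and 0.384 to 4.74 CPM in controls, and it was not called (adjusted p = 0.188). Without mutant replicate 2 the rises numbered 4 and the median was 0.33. The call of Fasn was lost without control replicate 2 or mutant replicate 3 and with the length trend removed, where the falls numbered 0 (largest adjusted p 0.0607).

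Genes of proliferation, of cholesterol synthesis and of glycolysis were more often lower than higher. Of 34 cell cycle genes 1 rose and 10 fell (1 and 14 adjusted over the list alone). Cenpf fell from 94.4 ± 7.53 to 61.2 ± 5.05 CPM (log2 fold change -0.63), Ccne2 by 0.79, and Mki67, a proliferation marker, from 329 ± 5.63 to 254 ± 6.1 CPM (-0.37). The list was called lower (median -0.20, adjusted p = 0.00099), and with an estimated correlation its adjusted p = 0.706. Of 21 genes of cholesterol synthesis and uptake 1 rose and 6 fell (1 and 12 adjusted over the list alone), among them Cyp51 (-0.84), Stard4 (-0.58) and Sc5d (-0.57). That list was called lower (median -0.44, adjusted p = 0.000208), and its adjusted p = 0.741 with an estimated correlation. Of 20 glycolysis and hypoxia genes 5 fell and none rose (6 and 0 adjusted over the list alone), with Hk2, a hexokinase, at -0.83, Egln3 at -0.77 and Pgam1 at -0.30. The list was called lower (median -0.17, adjusted p = 0.00545), and its adjusted p = 0.531 with an estimated correlation. Falls among cell cycle genes numbered 5 without control replicate 2 or 3 or mutant replicate 2 or 3, and rises 2 without mutant replicate 2. Falls among cholesterol genes numbered 3 without control replicate 2, 2 without control replicate 3 or mutant replicate 3, and 14 without mutant replicate 1. Rises numbered 0 when any library but mutant replicate 3 was left out, and the call of Cyp51 was lost without control replicate 3 or mutant replicate 3 (largest adjusted p 0.0597). Falls among glycolysis genes numbered 2 without control replicate 2 and 3 without control replicate 3 or mutant replicate 1 or 2, and without mutant replicate 3, 1 rose. The call of Pgam1 was lost without control replicate 2 or mutant replicate 2 or 3 (largest 0.0711).

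Response genes downstream of growth factors, TGF-beta and inflammation were not called as sets. Of 24 growth factor and ERK response genes 2 rose and 4 fell (2 and 6 adjusted over the list alone). Spry1, a feedback inhibitor of receptor tyrosine kinases, rose by 0.51 on the log2 scale, while Fosl2 fell by 0.53 and the growth factor gene Ereg by 1.51. The set was not called (median -0.04, adjusted p = 0.466). Without control replicate 1 it was called lower (adjusted p = 0.0159), with 8 falls and a median of -0.18. The median was 0.02 without control replicate 2, -0.08 without mutant replicate 3 and -0.01 without control replicate 3 or mutant replicate 1 or 2. Falls numbered 2 without control replicate 3 or mutant replicate 2 or 3, and rises 1 without any 1 control library or mutant replicate 2. The call of Fosl2 was lost without control replicate 3 (0.0522). Of 18 TGF-beta response genes 2 rose and 1 fell (3 and 2 adjusted over the list alone), with Tgfbi at -0.52, Ltbp1 at 0.30 and Tgfb2 at 0.41, and the set was not called (adjusted p = 0.914). Its direction turned without control replicate 2 (0.902) and mutant replicate 2 (0.721). Rises numbered 0 without control replicate 2 or mutant replicate 1 or 3 and 1 without control replicate 1 or 3, and falls numbered 3 without control replicate 1. Ltbp1 lost its call when any library but mutant replicate 2 was left out (largest adjusted p 0.147), and Tgfb2 when any but control replicate 3 was (0.123).

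Of 17 inflammatory genes 2 rose and 1 fell, also over the list alone. Icam1, a leukocyte adhesion molecule, fell from 144 ± 20.3 to 51.4 ± 6.03 CPM (log2 fold change -1.49), and the chemokine genes Cxcl14 (0.63) and Cxcl12 (0.34) rose. The set was not called (adjusted p = 0.952), with a median of -0.18, a mean of -0.06 and a test direction towards higher. That direction turned without control replicate 1 (0.486) or 2 (0.541) and without mutant replicate 1 (0.818) or 2 (0.586). The median was 0.16 without control replicate 3, -0.12 without control replicate 1, and -0.09 without mutant replicate 2 or 3. Rises numbered 1 and the call of Cxcl12 was lost without control replicate 2 or 3 or mutant replicate 1 or 2 (largest adjusted p 0.167). Falls numbered 3 without control replicate 1 or mutant replicate 2 and 2 without control replicate 2.

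Some marker lists of cell types other than mural cells and fibroblasts were called by camera with its preset correlation, and none with an estimated one. Of 17 tested markers of skeletal muscle and satellite cells 13 rose and none fell (16 and 0 adjusted over the list alone), with a median log2 fold change of 1.33. Cdh15, an adhesion molecule of satellite cells, rose from 11.9 ± 1.78 to 25.9 ± 5.37 CPM. Leaving out 1 library at a time left between 9 and 14 rises, the fewest without mutant replicate 3. Of 18 endothelial markers 7 rose (9 over the list alone, median 0.66), Lyve1 with the smallest adjusted p, with a median of 0.41 without mutant replicate 3. Of 6 mast cell markers 4 rose (6 over the list alone, median 0.65), Tpsb2 with the smallest adjusted p (log2 fold change 1.24). Of 20 keratinocyte markers 7 rose and none fell (7 and 1 over the list alone, median 0.36), and Perp, the one with the smallest adjusted p, rose by 0.59 on the log2 scale. These rises numbered 2 without control replicate 3 or mutant replicate 3 and 3 without mutant replicate 1, and 1 marker fell without control replicate 1. Of 9 melanocyte markers 2 fell, also over the list alone, with Mitf at -0.53 and a median of -0.62. Control replicate 1 stood apart in this list. Slc45a2, chosen after its values were seen, had 18.3 CPM there, 4.36 and 5.63 CPM in the other controls and 2.93 to 4.07 CPM in mutants, and it was not called (adjusted p = 0.215). Without control replicate 1 the median was -0.44. The list was called lower whichever library was left out (largest adjusted p 0.0303). The melanocyte falls numbered 1 without control replicate 2 or 3 or mutant replicate 1. Camera called the muscle (adjusted p = 2.09e-08), endothelial (0.000224), mast cell (0.000412) and keratinocyte (0.00628) lists higher and the melanocyte list lower (0.00545). With an estimated correlation none of these calls held, at adjusted p = 0.584 for muscle, 0.706 for endothelium, 0.531 for mast cells, 0.741 for keratinocytes and 0.741 for melanocytes. Without mutant replicate 3 the keratinocyte list was not called (adjusted p = 0.0579).

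Of 17 Schwann cell markers 1 rose and 2 fell (1 and 4 over the list alone), and the set was not called (adjusted p = 0.168). Without mutant replicate 3 it was called lower (0.0448), with 1 fall and 0 rises, and without control replicate 1 or mutant replicate 1 the rises numbered 0. None of 15 macrophage markers was called by edgeR, DESeq2 or limma-voom, 2 were by limma-voom with sample weights, and 3 had an unadjusted edgeR p under 0.05 (median 0.19, adjusted p of the set 0.0984). Mrc1 among them had 89.9 ± 15.8 and 100.3 ± 7.48 CPM. Without control replicate 1 the macrophage list was called higher (adjusted p = 4.79e-05), with 8 rises and a median of 0.65. The median was 0.03 without control replicate 2 and 0.12 without mutant replicate 3. Only 2 erythroid genes were tested, and the list was not. Neither was called by edgeR, DESeq2 or limma-voom, both had an unadjusted edgeR p under 0.05 (2 adjusted over the list alone), and 1 was called without control replicate 2 or mutant replicate 2. Hba-a1 had 0.86 ± 0.491 and 2.18 ± 1.32 CPM.

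Genes of the dissociation and heat shock list moved in 2 directions. Of 20 tested 3 rose and 7 fell, also over the list alone. Hsph1, a heat shock protein, fell from 79.3 ± 7.42 to 36 ± 2.68 CPM (log2 fold change -1.14, edgeR adjusted p = 3.35e-05). The genes that rose were the immediate early genes Jun (0.58), Jund (0.83) and the cytokine signalling inhibitor gene Socs3 (0.53), chosen after their values were seen. The set was not called (adjusted p = 0.812), and its median of 0.24 and mean of -0.11 differed in sign. Without control replicate 1 the median was 0.01, and without control replicate 2 it was 0.37. The direction of the test turned without control replicate 2 (0.831) or 3 (0.923), where the falls numbered 4, and without control replicate 1 the rises numbered 6.

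None of 15 interferon response genes was called by edgeR, DESeq2 or limma-voom, and 1 had an unadjusted edgeR p under 0.05 (median -0.92, adjusted p of the set 0.31). Ifit2 had 46.4 ± 4.69 and 38.1 ± 3.19 CPM. Without control replicate 1 the direction of the interferon list turned, with a median of 0.65, an adjusted p of 0.0182 towards higher and 3 rises, and without control replicate 2 it was called lower (0.00944). Without control replicate 2 or mutant replicate 2, 1 of these genes was lower. Of 10 mitochondrially encoded genes 5 rose (8 over the list alone, median 0.63), and mt-Cytb, the one with the smallest adjusted p, rose from 818 ± 81.8 to 1184 ± 182 CPM (log2 fold change 0.53). That list was called higher (adjusted p = 0.000821), and its adjusted p = 0.706 with an estimated correlation. The rises numbered 3 without control replicate 1 or 3 or mutant replicate 1. They numbered 1, and the call of mt-Cytb was lost (adjusted p = 0.0753), when a trend with gene length was removed.

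Sex-linked genes differed within the mutant group. Of 4 tested sex-linked genes none was called by edgeR, DESeq2 or limma-voom, 0 had an unadjusted edgeR p under 0.05, and the list was not tested. Without mutant replicate 1, 1 of them was lower. Ddx3y, a gene of chromosome Y, had 103 ± 12 CPM in controls and 59 ± 51.2 CPM in mutants, with 0.201 CPM in mutant replicate 1 and 93.5 and 83.2 CPM in the other 2. Its log2 fold change was -0.80 (edgeR adjusted p = 0.712), -0.23 without mutant replicate 1 and -1.28 without mutant replicate 2, and limma-voom with sample weights gave the lowest value, -3.05.

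**Figure D2:**
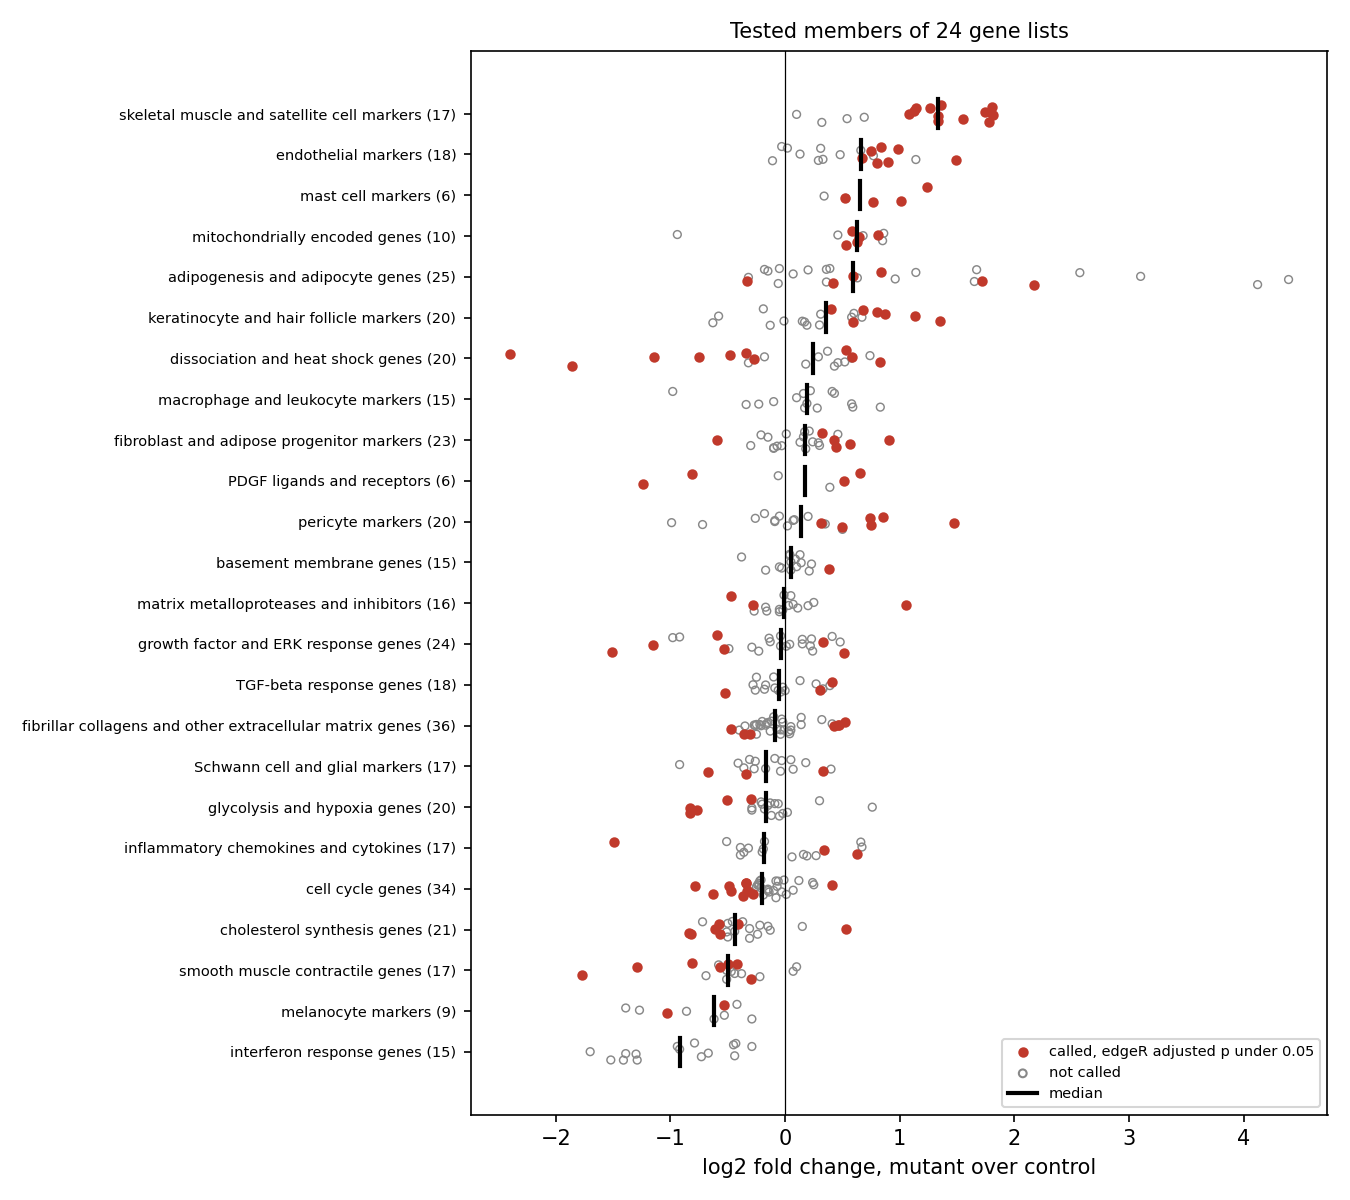
Log2 fold change, mutant over control (horizontal axis), of the tested members of 24 gene lists, with the number tested in brackets. Filled points were called by edgeR, open points were not, and black bars are list medians. The muscle list sits farthest to the right, with a median of 1.33, and the interferon list farthest to the left, with a median of -0.92 and no called gene.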

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

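Of the tests in this part, those of the other 95 genes of the MHC region and of the second muscle list were written before their values were seen, and the others after. Reads aligned to more than 1 place, which the gene tests do not use, were a larger share of the listed reads in every mutant library than in any control. The share was 5.39% ± 0.367 in controls and 6.31% ± 0.183 in mutants (SD, n = 3 per group, exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). Mutant replicate 1 held 13179 counts of Xist, the RNA of the inactive X chromosome, and the other 5 libraries held at most 5, so that library came from a female and the others did not show an inactive X. Without mutant replicate 1, 879 genes were higher and 1086 lower.

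The first pattern is the fall of Pdgfra. Library scaling as its cause is argued against by the log2 fold change closest to 0 under 3 other scalings, -1.21. Fewer fibroblasts or progenitors among the sorted cells is argued against by the median of their markers, 0.17 (0.11 without control replicate 3), with quartiles of -0.08 and 0.31. Loss of the counted reads of 1 allele, which would give a log2 fold change of -1, stays open, since the upper 95% limit was -1.07, and -0.99 with the length trend removed, gene counts do not separate the alleles, and the "[S]" in the allele's label is unexplained. A lower level of the receptor transcript in cells with the active receptor is an untested hypothesis.

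The second pattern is a near-complete loss of some near-identical pseudogenes and a shift of class I H2 genes. Over 8-fold lower were 14 called genes, 8 of them annotated pseudogenes and 5 without a symbol, and none was over 8-fold higher, and of 13 class I H2 genes, paralogs whose reads are uncertain, 6 were lower and 1 higher. Alignment settings that differed between the groups are argued against as a whole cause by 61 pseudogenes at least 98% identical to their parent transcript, whose median was 0.37 (bootstrap interval 0.12 to 0.55) while 9 of them were called lower, 7 at least 4-fold, and 5 higher, 1 at least 4-fold, although the share of multiply aligned reads was higher in mutants. Lower interferon signalling is argued against for the H2 genes by 5 class I H2 genes still lower without control replicate 1. There the interferon list was higher by camera with its preset correlation (adjusted p = 0.0182). Without control replicate 2 that list was called lower (0.00944), so its direction depended on the library left out. Strain sequence across the MHC region stays open. Its other 95 genes were called in 10.5% of cases (odds ratio 0.545, 95% interval 0.252 to 1.05, Fisher's exact two-sided p = 0.0783), but that set left out the H2 genes and 3 called genes noticed there before, so it excludes nothing. With these the region had 20 of 111 genes called, 18% against 17.8% elsewhere (odds ratio 1.02, 95% interval 0.593 to 1.67, Fisher's exact two-sided p = 0.901). Sequence differences between strains stay open too, whether in single genes or copies or across the genome. No strain or read sequence was analysed here. The 7 pseudogenes at least 4-fold lower lay on 7 chromosomes. A strain background that differed between the groups could not be told apart from the genotype.

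The third pattern is the rise of skeletal muscle markers. A smaller share of the main cell type would raise other markers alike. It was tested on the Schwann list only, which argues against it as the whole cause. The muscle median exceeded the Schwann median by 1.5, against a spread of 0.52 taken from the quartiles of the genes in both lists. Other list medians were positive for endothelium (0.66), mast cells (0.65), keratinocytes (0.36) and macrophages (0.19). They were negative for melanocytes (-0.62) and Schwann cells (-0.17), so a part in the rise stays open. More RNA of the whole muscle lineage was tested on a second list of muscle genes, of which 16 of 40 were higher and none lower (median 0.63), short of the majority predicted, so it may account for part of the pattern and stays open. Of the first list 1 member is also in the contractile list, its marker Actc1 reached 77.7 ± 18.3 CPM, and the Nestin-GFP gate would not remove satellite cells if these express the reporter. A change of muscle cell number or state in mutant skin was not tested.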

How the results depend on the processing

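Removal of the length trend was chosen after seeing the data. No called gene changed sign under any of 17 alternatives. The groups did not overlap in 2653 of the 2670 called genes, so leaving out 1 library could hardly turn the sign of those. The alternatives shared between 50.4% (without mutant replicate 3) and 100% of the calls. The 100% came from removal of 4 sex-linked genes, none of them called, and so was fixed in advance. The next highest share was 98.35%, with the filter of 1 CPM in 3 libraries. Of 66 named genes that were called, 49 kept their side of the threshold throughout and 17 lost it at least once. Pdgfrb, never called, had -0.06, and -0.10 to 0.00 with 1 library left out, turning without control replicate 1. Genes higher and lower numbered 222 and 170 at 2-fold or more, 658 to 1199 and 753 to 1500 with 1 library left out, and 1328 and 1439 with the replicate number as a block. Deviations of libraries with the same number in their titles had r = 0.12, -0.03 and -0.09 over genes. The deposited files number the mutants from 2 instead, which would match control replicate 2 with mutant replicate 1 (-0.06) and 3 with 2 (0.16). These correlations did not show a pairing by the numbers of the titles, used for the block, and did not exclude one. Not every library correlated best with its own number. Under the block the macrophage list became called (adjusted p = 0.0362).

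The 11 list calls became 0 with an estimated correlation and numbered 11 to 15 with 1 library left out. With an estimated correlation, adjusted p-values were 0.706 (smooth muscle, cell cycle, endothelial, mitochondrial), 0.741 (adipocyte, cholesterol, melanocyte, keratinocyte), 0.531 (glycolysis, mast cell) and 0.584 (skeletal muscle). Fry, a different test that asks for a shift of a list in 1 direction, called 4 lists. These were glycolysis and mast cell (0.0213), skeletal muscle (0.0363) and PDGF (0.0434), the last not called by camera. Fry gave 0.126 (smooth muscle, endothelial, mitochondrial), 0.267 (adipocyte), 0.0671 (cell cycle), 0.202 (cholesterol), 0.227 (melanocyte) and 0.235 (keratinocyte). Direction for the inflammatory list was the opposite by fry (0.87) and turned with the length trend removed (0.93), and for the TGF-beta list with that trend removed (0.965). With 1 library left out, adjusted p ran from 0.0159 to 0.845 (ERK response), 0.0400 to 0.923 (matrix), 0.0282 to 0.392 (pericyte), 0.0299 to 0.406 (fibroblast), 0.508 to 0.923 (TGF-beta), 0.378 to 0.818 (inflammatory), 0.0448 to 0.412 (Schwann), 0.000442 to 0.0579 (keratinocyte), 4.79e-05 to 0.688 (macrophage), 0.503 to 0.923 (heat shock) and 0.00944 to 0.473 (interferon). Fewer libraries lower the power of those fits, and the cause was not tested otherwise. DESeq2 gave no adjusted p for 591 genes, and Ddx3y had no value without sex-linked genes. At this depth, genes near 0.16 to 0.252 CPM were at the limit of detection.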

Other observations

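All tests of this part were chosen after results were seen, and the list of imprinted genes was written after 4 of its members had been noticed. Of 24 tested imprinted genes 10 rose, 13 were not called and 1 fell, and the list had p = 0.146 by camera with an estimated correlation. Dlk1, an inhibitor of fat cell differentiation, rose from 1206 ± 214 to 3091 ± 231 CPM (log2 fold change 1.36, edgeR adjusted p = 8.4e-05). Igf2, a growth factor, rose from 1980 ± 90.9 to 3547 ± 304 CPM (0.84), and the noncoding RNA gene H19 beside it from 2220 ± 103 to 3684 ± 134 CPM (0.73). Cdkn1c, a cell cycle inhibitor (1.04), Rtl1 (1.41), Mest (0.79) and Plagl1 (0.73) rose as well. Peg3 (-0.21), Meg3 (0.18) and Grb10 (0.19) were among those not called. The number of rises lay between 8 and 11 over the alternatives.

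The hypothesis of a joint rise was tested on the 20 members that had not been noticed beforehand. Of these 6 rose, and 2.41% of 10000 random lists matched on mean expression held as many. The random lists held a median of 2 and a 95th percentile of 5. The 6 rises exceed that 95th percentile, the outcome predicted for a joint rise. They include H19, which lies beside Igf2, a gene noticed beforehand. Igf2r and Gnas among them were near the threshold (edgeR adjusted p = 0.0314 and 0.0409). The random lists were drawn gene by gene and do not allow for members that change together. The count therefore does not settle a joint rise. In the same comparison 13 of 17 skeletal muscle, 7 of 18 endothelial and 4 of 6 mast cell markers were called higher. The list medians were 1.33, 0.66 and 0.65, and the calls of these lists by camera were lost with an estimated correlation. Whether a different mix of cells lies behind the imprinted genes was not tested. Camera gave p = 0.000127 for the whole list with a preset correlation and p = 0.146 with an estimated one. The result by camera therefore depends on that setting, and why it does was not tested.

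Ribosomal protein genes were mostly higher, with 65 of 77 rising and none falling (median log2 fold change 0.37). With a trend of fold change on gene length removed, 44 were higher and the median was 0.29. That trend ran across all tested genes, with Spearman's rho of -0.20 over genes, which are not independent replicates.

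Some near-identical pseudogenes were uneven within a group, and their reads are uncertain. Rpsa-ps10 had 852 and 1041 counts in mutant replicates 1 and 3 and 14 in mutant replicate 2, with 3 to 6 in controls. Gm8730 had 934 counts in mutant replicate 2 and 11 to 28 in every other library. EdgeR called neither (adjusted p = 0.107 and 0.276). Rps15a-ps6 had 145 counts in control replicate 3 and 197 in mutant replicate 3, against 23 to 51 elsewhere.

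The 6 libraries can be divided into groups of 3 in 10 ways, too few for a share under 0.05. The real division gave 1298 genes higher and 1372 lower and was the 1 division with as many in either direction. The highest among the others was 0 higher and 2 lower. Each of the others held controls and mutants on both sides, so a real difference between mutants and controls would count as spread there. Few gene calls from them therefore give no chance level. For gene lists the real division called 11, and the highest of the others 12. Of the 10 divisions 4, the real one included, called as many. The other divisions still held part of the difference between mutants and controls, so their list calls give no chance level either.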
